A study of Homo sapiens with 6 samples.

How the data were processed

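Single-cell RNA sequencing measured gene expression in skin biopsies from 3 people with granuloma annulare and 3 healthy people, 1 library per biopsy. Per the labels' protocols, each punch biopsy was digested with dispase and then with liberase, red cells were lysed, live cells were sorted, and CD45 was recorded without being used to choose cells. The live cells went onto a 10x Chromium controller, per the labels' protocols. The submitters' processing notes name Cell Ranger 3.1.0, Seurat without a version, R 3.1.5 and the genome build hg38, with no role or order for each.

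The deposited values are natural log values, of 1 plus 10000 times a gene's share of the cell's unique molecular identifiers (UMIs). With the natural log undone, every cell of the deposited tables summed to 10000, and every value was a whole multiple of its cell's smallest step within a tolerance of 0.01. UMIs per gene and cell could therefore be worked back. How the authors chose the barcodes in the files is not stated by the labels, and no barcode in the files had over 12.0% mitochondrial UMIs. The files held 33538 genes for 6310, 1367 and 3867 barcodes of granuloma annulare 1, 2 and 3 and for 819, 4813 and 2590 barcodes of healthy 1, 2 and 3. The worked-back UMIs came to 45559880, 15996838 and 23660262 in the granuloma annulare samples and to 10061212, 32972423 and 4239593 in the healthy samples.

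Barcodes with at least 200 genes and under 20% mitochondrial UMIs were kept. Scrublet scores, from scanpy 1.11.5, were ranked per sample, and the top 0.8% for each 1000 barcodes were removed as doublets. Removal followed the clustering, which included them. This left 5970, 1325 and 3712 cells of granuloma annulare 1, 2 and 3 and 790, 4616 and 2406 cells of healthy 1, 2 and 3. Cells of all samples were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1 and seed 0 (leidenalg 0.10.2), without batch correction. A cluster took a class name when at least 3 markers of that class, fixed beforehand, were among its top 50 genes seen in at least 15% of its cells. After the clusters were seen, clusters of shallow cells, with a median UMI count under 0.333 of that of their own sample, were required to have 3 markers among their top 10 genes, and clusters led by plasmacytoid dendritic genes were left unnamed. A class name says only which markers a cluster holds.

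For each class and sample with at least 10 cells of the class, the values with the log undone were averaged over cells and expressed per 1000000 UMIs. A gene was tested when it reached the equivalent of 10 UMIs at the median library depth in at least 3 samples, or in as many as the smaller group holds, and had at least 15 UMIs in all. Scaling factors were trimmed means of log ratios, with 0.3 of the ratios and 0.05 of the levels trimmed. A pseudocount worth 2 UMIs of the shallowest library was added before taking log2, which came per 1000000 UMIs to 6.65 in the fibroblast-like, 32.7 in the myeloid-like, 10.8 in the T/NK-like, 3.46 in the blood endothelial-like, 11.9 in the mural-like and 8.25 in the keratinocyte-like class. This pseudocount was chosen after seeing that 2 UMIs of the mean library put the median of all genes in the myeloid-like class at 0.423. With the pseudocount chosen it was 0.062. Log2 differences are granuloma annulare minus healthy on this scale, so they understate differences in genes near the pseudocount. Leaving out 1 sample reset the filter, the scaling factors and the pseudocount. Without the shallowest library the pseudocount shrank, so sizes from that fit are not comparable with the others. The shallowest library was healthy 3 in the fibroblast-like, myeloid-like, T/NK-like and mural-like classes. It was healthy 1 in the blood endothelial-like and granuloma annulare 3 in the keratinocyte-like class. Each class was tested with limma 3.58.1 (moderated test with trend and robust options, R 4.3.3, statmod 1.5.0) and Benjamini-Hochberg adjustment at 0.05 over the genes of the class. Every adjusted p of a gene below is from that limma test. Only samples served as replicates, never cells.

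Gene lists, fixed beforehand, were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all 138 pairs of list and class that had at least 3 tested genes. Each list was tested again with a correlation estimated from the data, and with limma's fry. Members past 0.05 were counted with adjustment over all genes of the class and adjusted over the list alone. Differences between classes in the size of the granuloma annulare change were tested for 10 pairs of classes with limma on the within-sample differences. Each class kept its own pseudocount there, so for genes near it the classes are not on the same scale. Shares of cells were compared with a 2-sided exact permutation test, whose smallest p for 3 against 3 is 0.1.

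Before the data were examined, the grouping, the comparisons, the cell filter, the markers, the gene lists, the key genes and the rule for naming genes were fixed. By that rule the text names, per class, up to 10 higher and 10 lower genes with the largest log2 difference among those past 0.05 with a mean of at least 20 per 1000000 UMIs and no overlap between the groups. It also names up to 4 genes with the smallest p of each list discussed, and the key cytokine and cell-state genes. Chance alone separates 3 samples from 3 without overlap in 10% of genes. XIST, Y-linked genes, variable segments of antigen receptors and genes whose level follows common haplotypes or copy number, 741 genes in the files, were left out of the named genes and lists. After the results were seen, 1 further called gene whose copy number varies among people was counted but not named. The count model planned before the files were seen was not fitted, as the deposited values are log values, and the limma test on log2 values took its place, with voom on sums of the worked-back UMIs as an alternative. Gene positions are from GENCODE release 29 on GRCh38 (hg38).

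The test was first run on simulated data with the real samples' depths. Each simulated gene took a reduced part of the variance of a real gene drawn at random, plus counting error. Genes varied independently, and levels came from summed UMIs rather than means over cells. The recovery and false shares below hold for that setting, which may be easier than the real data. It recovered 74.6%, 50.0%, 50.0%, 82.3%, 72.6% and 0% of 4-fold changes in the fibroblast-like, myeloid-like, T/NK-like, blood endothelial-like, mural-like and keratinocyte-like classes. The false share of its calls was 2.4%, 1.4%, 1.2%, 3.2%, 3.4% and 8.3% in the same order, on 10848, 10431, 12389, 10721, 5746 and 5542 genes. The number labels of the samples pair nobody, and the biopsies came from separate people on separate days, per the labels' protocols, so person and day cannot be told apart. No batch is labelled. The UMIs of the 3 libraries of each group differed beyond counting error in all 6 pairs (lowest chi-square per degree of freedom 86), so the check found no library deposited 2 times, and it says nothing on other kinds of repeats.

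The alternatives tried were median-ratio scaling, the per-cell scaling alone, no filter on low values, other pseudocounts, leaving out each sample, a stricter cell filter (500 genes and 10% mitochondrial UMIs), doublets kept, Leiden resolution 0.5, and a replicate block. Chosen after seeing the data were the pseudocounts, the per-cell scaling, sums of UMIs with and without voom weights, leaving out shallow clusters, and leaving out keratinocyte-like cells with sweat gland transcripts. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.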

Results

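Gene expression was measured in single cells of skin from 3 people with granuloma annulare, an inflammatory skin disease in which macrophages gather in the dermis, and of skin from 3 healthy people. The series title names tofacitinib, a drug that blocks the Janus kinases used by many cytokine receptors, and cytokine activity. The comparison therefore asks which cytokines and which responses to them differ between granuloma annulare and healthy skin, cell type by cell type. The labels put no sample in a treated group and do not say whether the granuloma annulare skin was untreated or came from a lesion, so both stay unknown here. The samples held 45559880, 15996838 and 23660262 UMIs in granuloma annulare 1, 2 and 3 and 10061212, 32972423 and 4239593 in healthy 1, 2 and 3. Median UMIs per cell ranged from 4879 to 7694 in granuloma annulare, and were 12107, 5568 and 1132 in healthy 1, 2 and 3, so healthy 3 was the shallowest library. Levels below are means ± SD of UMIs per 1000000, averaged over cells and then over the biopsies of a group, with n = 3 per group unless stated. Log2 differences are granuloma annulare minus healthy ± SE.

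B and plasma cell-like cells, the antibody-making lineage, made up 4.83% ± 2.74 of the kept cells in granuloma annulare and 0.094% ± 0.163 in healthy skin (n = 3 each, exact permutation p = 0.1, 0.4 after adjustment over the 10 classes). They numbered 134, 60 and 286 cells in granuloma annulare 1, 2 and 3 against 0, 13 and 0 in healthy 1, 2 and 3, where a count of 0 allows shares of up to 0.38% in healthy 1 and 0.125% in healthy 3. T and natural killer cell-like (T/NK-like) cells made up 65.3% ± 10.6 in granuloma annulare and 29.98% ± 33.7 in healthy skin (exact p = 0.2, 0.4 after adjustment). Keratinocyte-like cells, the epithelial cells of the epidermis and its glands, made up 0.487% ± 0.104 and 2.43% ± 2.36 (exact p = 0.1, 0.4 after adjustment). Myeloid-like cells made up 6.33% ± 2.99 and 7.58% ± 5.96 (exact p = 0.8). The B and plasma cell-like and keratinocyte-like shares were the 2 without overlap between the groups, and without granuloma annulare 2 or without healthy 2 there were 5. No share could pass 0.05, since 0.1 is the smallest p for 3 against 3, and the healthy biopsies differed widely among themselves.

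**Figure D1:**
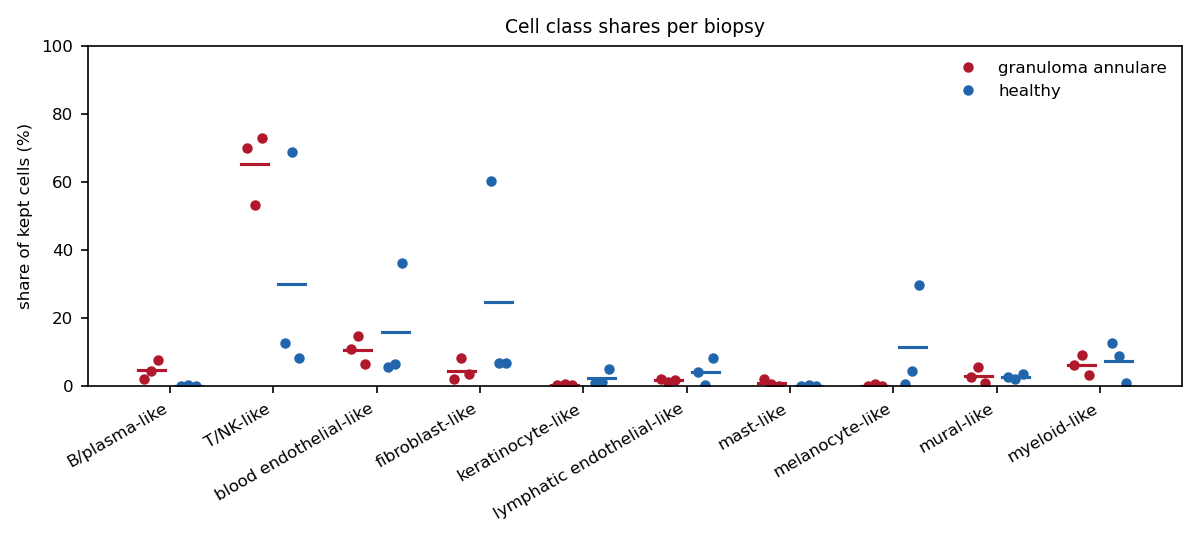
Share of the kept cells (percent) in each cell class, 1 point per biopsy, with granuloma annulare and healthy shown side by side and a bar at the mean of the 3 biopsies. The B and plasma cell-like share averaged 4.83% in granuloma annulare and 0.094% in healthy skin.

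In the T/NK-like class, transcripts of IFNG, which encodes interferon gamma (GRCh38 chromosome 12, 68154768 to 68159747), rose from 76.0 ± 35.9 in healthy skin to 315 ± 75.01 in granuloma annulare, a log2 difference of 2.13 ± 0.32 (adjusted p = 0.0489). CXCL13, a chemokine that attracts B cells (chromosome 4, 77511753 to 77611834), rose from 0.569 ± 0.985 to 90.4 ± 50.6 (log2 3.09 ± 0.36, adjusted p = 0.0141). GIMAP4 rose from 20.7 ± 6.89 to 190 ± 36.6 (adjusted p = 0.0141) and GIMAP7 from 53.4 ± 5.23 to 273 ± 60.4 (adjusted p = 0.0308), both GTPases of lymphocytes. The interferon-inducible gene GBP4 rose by a log2 difference of 1.82 ± 0.28 (adjusted p = 0.0489), and EOMES, a transcription factor of cytotoxic cells, by 1.62 ± 0.24 (adjusted p = 0.0488). NTRK2 fell from 51.9 ± 19.4 to 2.37 ± 0.43 (adjusted p = 0.0261) and the amino acid transporter gene SLC16A10 from 61.3 ± 18.1 to 6.85 ± 2.10 (adjusted p = 0.0308). IL13, a type 2 cytokine gene, averaged 8.25 ± 5.85 against 43.4 ± 1.5 and did not pass (log2 -1.44, adjusted p = 0.173). GZMK, which encodes a granzyme, and CCR6, a chemokine receptor of type 17 helper cells, also missed the threshold, with log2 differences of 3.01 (adjusted p = 0.0522) and -2.31 (adjusted p = 0.0507). IL4 and IL17A reached the level of the filter in too few samples to be tested. IL4 had 46, 5 and 8 UMIs in granuloma annulare 1, 2 and 3 against 1, 5 and 0 in healthy 1, 2 and 3. IL17A had 19, 0 and 0 against 2, 65 and 0, so 1 biopsy per group held most of its UMIs. These UMIs are not scaled to the depth of the libraries.

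Of the 12613 genes tested in the T/NK-like class, 7 rose and 2 fell, and 991 had an unadjusted p under 0.05. Under median-ratio scaling 4 were higher and 2 lower, with voom on sums of UMIs 19 were higher and 22 lower, and 29 were higher and 23 lower without healthy 1. Leaving out granuloma annulare 1, 2 and 3 gave 3, 3 and 0 genes, and leaving out healthy 1, 2 and 3 gave 52, 0 and 10 (limma, with 750 and 1356 genes at an unadjusted p under 0.05 in the fits that called 0). IFNG had an adjusted p of 0.184, 0.0897 and 0.286 without granuloma annulare 1, 2 and 3 and 0.192 without healthy 2, and CXCL13 had 0.2 and 0.0803 without granuloma annulare 3 and healthy 2. No gene passed in all 6 of these fits.

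Among the gene lists in the T/NK-like class, the 18 tested cytotoxic genes had a median log2 difference of 0.96, with 1 higher over all genes and 7 adjusted over the list alone. For the cytotoxic list camera gave adjusted p = 5.11e-08, and adjusted p = 0.376 with an estimated correlation. EOMES, GZMK, KLRG1 (log2 1.67) and CCL5 (log2 1.92, adjusted p = 0.322) had the smallest p values of that list. The 25 tested genes of the IFN-gamma response had a median of 0.66, with 1 higher over all genes and 8 adjusted over the list alone, and GBP4, ETV7, GBP1 and GBP5 led it. For the IFN-gamma response camera gave adjusted p = 4.93e-08, and adjusted p = 0.225 with an estimated correlation. The 10 naive and central memory genes had a median of 0.78, with 1 higher over all genes and 5 adjusted over the list alone, with KLF2 (828 ± 253 against 224 ± 105) and CCR7 (214 ± 77.1 against 68.9 ± 31.9) among its members. For the naive and central memory list camera gave adjusted p = 2.05e-06, and adjusted p = 0.255 with an estimated correlation. The 6 type 2 helper genes had a median of -0.997, with 0 lower over all genes and 1 adjusted over the list alone, led by IL13, IL17RB and CCR8. For the type 2 helper list camera gave adjusted p = 2.12e-05, and adjusted p = 0.202 with an estimated correlation. The 7 type 17 helper genes had a median of -0.59, with 0 lower over all genes and 2 adjusted over the list alone, led by CCR6 and IL1R1. For the type 17 helper list camera gave adjusted p = 0.000953, and adjusted p = 0.226 with an estimated correlation. The 13 type 1 helper genes had a median of only 0.08 and 1 member higher over all genes, IFNG, with 4 adjusted over the list alone (camera adjusted p = 0.0311, adjusted p = 0.258 with an estimated correlation). That call ended without granuloma annulare 3, healthy 1 or healthy 2, with a highest adjusted p of 0.111. CXCR3, CCL5 and TBX21, a chemokine receptor, a chemokine and the transcription factor of type 1 helper cells, stood beside IFNG with log2 differences of 1.46, 1.92 and 0.91, none past the threshold. Transcripts typical of fibroblasts were lower in this class in granuloma annulare (median -0.84, 0 of the tested genes past the threshold either way, camera adjusted p = 3.11e-06, adjusted p = 0.366 with an estimated correlation), and so were those of keratinocytes (median -0.725, 0 past the threshold either way, camera adjusted p = 0.000382, adjusted p = 0.398 with an estimated correlation). Macrophage and dendritic transcripts were higher (median 0.353, 0 past the threshold either way, camera adjusted p = 0.00535, adjusted p = 0.409 with an estimated correlation), a call lost without granuloma annulare 1 and healthy 2 (0.0832 and 0.147). Their median was 0.567 without healthy 1 and 0.624 without healthy 3. B and plasma cell transcripts were higher (median 0.49, 0 over all genes and 2 of 6 adjusted over the list alone, camera adjusted p = 0.000195, adjusted p = 0.228 with an estimated correlation). Without 1 sample the median of the cytotoxic list ran from 0.62 (without healthy 2) to 1.378 (without healthy 1), and that of the type 2 helper list moved to -0.597 without healthy 2. The medians moved to -0.318 for the type 17 helper list (without granuloma annulare 2) and to 0.045 and 0.499 for the type 1 helper list (without healthy 2 and healthy 3). Without healthy 3 the B and plasma cell transcripts moved to 1.05 and the keratinocyte transcripts to -0.228 (adjusted p = 0.0733). The fibroblast transcripts moved to -0.469 without healthy 1 and -1.347 without healthy 2. Granuloma annulare T/NK-like cells lay mostly in clusters 0, 1, 3, 4 and 8, those of healthy 2 in clusters 2, 6 and 11, and those of healthy 3 in the shallow cluster 20. Leading genes included GZMK and IFNG in cluster 1, CXCL13 and IFNG in cluster 8, and CCR4 and CCR6 in cluster 2. No change was tested within a cluster. The changes of this class, IFNG and CXCL13 among them, therefore cannot be told apart from a different mix of T cells.

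**Figure D2:**
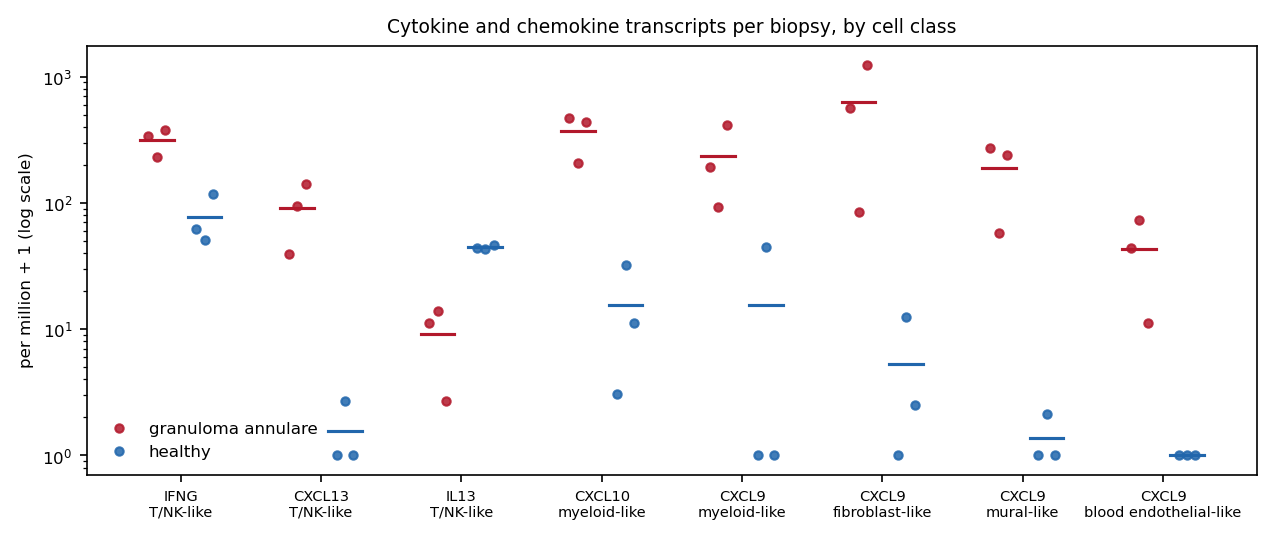
Levels of cytokine genes (UMIs per 1000000 plus 1, log axis) in the cell class named under each panel, 1 point per biopsy, with a bar at the mean of the 3 biopsies of granuloma annulare or healthy skin. In the T/NK-like class the mean level of IFNG was 315 against 76.0 and that of IL13 was 8.25 against 43.4, the latter not past the threshold.

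In the myeloid-like class, FN1, which encodes the matrix protein fibronectin (chromosome 2, 215360440 to 215436172), rose from 3.84 ± 3.36 to 2167 ± 782 in granuloma annulare, a log2 difference of 5.92 ± 0.37 (adjusted p = 2.44e-06). SPP1, which encodes the secreted protein osteopontin (chromosome 4, 87975650 to 87983426), rose from 55.3 ± 52.8 to 1862 ± 897 (log2 4.66 ± 0.51, adjusted p = 0.0014). CXCL10, an interferon-induced chemokine (chromosome 4, 76021117 to 76023497), rose from 14.6 ± 15.2 to 371 ± 145 (log2 3.14 ± 0.38, adjusted p = 0.00241). FBP1, an enzyme of gluconeogenesis, rose from 44.6 ± 28.3 to 1552 ± 1217 (adjusted p = 0.00332), FCGR3A, an Fc receptor for IgG, from 11.4 ± 12.96 to 397 ± 136 (adjusted p = 0.0014), and IFI27, an interferon-stimulated gene, from 4.72 ± 3.91 to 244 ± 120 (adjusted p = 0.00332). The other genes to rise were LILRB4, an inhibitory receptor, SERPINA1, a protease inhibitor, and NUPR1, a stress-induced regulator, with log2 differences of 2.34, 2.20 and 2.12 and adjusted p values of 0.0281, 0.0252 and 0.0215. TNF, the tumour necrosis factor gene, averaged 160 ± 78.2 against 501 ± 223 (log2 -1.36, adjusted p = 0.297). IL1B, IL15 and OSM had log2 differences of -1.23, -0.13 and 0.03, none past the threshold.

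Of the 10658 genes tested in the myeloid-like class, 9 rose and 0 fell (limma, 1039 with an unadjusted p under 0.05, and 47 called by voom on sums of UMIs). FN1, FBP1 and FCGR3A passed in all 6 fits that left out 1 sample. The number changed was 9, 16 and 9 without granuloma annulare 1, 2 and 3, and 51, 6 and 22 without healthy 1, 2 and 3, and without healthy 3 SPP1 had a log2 difference of 6.73 (adjusted p = 0.133) and CXCL10 one of 5.11 (adjusted p = 0.0848). IFI27 lost the call without granuloma annulare 3 (log2 2.607, adjusted p = 0.0509) and had a log2 difference of 6.101 without healthy 3, LILRB4 without granuloma annulare 3 and healthy 2 (highest 0.168). SERPINA1 lost it without granuloma annulare 2 and 3 and healthy 2 (highest 0.127), and NUPR1 without granuloma annulare 1 and 3 and healthy 2 (highest 0.127). The log2 difference of NUPR1 ran from 1.913 to 3.529 over the 6 fits. Healthy 3 had 26 myeloid-like cells with 61175 UMIs. Leaving it out shrank the pseudocount, so the larger log2 differences of that fit are not comparable in size with those above.

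Among the lists in the myeloid-like class, the 7 metallothioneins, metal-binding proteins, had a median log2 difference of 2.17, with 0 higher over all genes and 7 adjusted over the list alone. For the metallothioneins camera gave adjusted p = 1.56e-09, and adjusted p = 0.255 with an estimated correlation. MT2A was 1570 ± 1524 against 116 ± 61.0 (adjusted p = 0.113), and MT1H, with no UMI in the healthy samples, was at least 26.1-fold higher against a floor of 3 UMIs in each healthy library. HLA class I presentation genes had a median of 1.12, with 0 higher over all genes and 11 of 17 adjusted over the list alone. For the HLA class I list camera gave adjusted p = 7.12e-11, and adjusted p = 0.202 with an estimated correlation. The immunoproteasome gene PSMB8 was 214 ± 52.6 against 50.6 ± 6.11. The 28 tested IFN-gamma response genes had a median of 0.89, with 1 higher over all genes, CXCL10, and 18 adjusted over the list alone. For the IFN-gamma response camera gave adjusted p = 1.32e-10, and adjusted p = 0.202 with an estimated correlation. GBP1, WARS and CXCL9 (233 ± 165 against 14.6 ± 25.3) had log2 differences of 2.00, 1.83 and 2.47, each with an adjusted p of 0.0841. The 22 lipid-handling and granuloma macrophage genes had a median of 0.80, with 1 higher over all genes, SPP1, and 12 adjusted over the list alone, with CYP27A1, ACE and CHI3L1 next. For the lipid-handling list camera gave adjusted p = 2.46e-08, and adjusted p = 0.226 with an estimated correlation. The 19 glycolysis and hypoxia genes had a median of 0.80, with 0 over all genes and, adjusted over the list alone, 9 higher and 1 lower, GAPDH at 2843 ± 1130 against 727 ± 211. For the glycolysis and hypoxia list camera gave adjusted p = 7.51e-06, and adjusted p = 0.307 with an estimated correlation. The 12 dendritic and Langerhans cell genes had a median of -0.82, with 0 lower over all genes and 2 adjusted over the list alone, CD1C at 59.3 ± 35.7 against 294 ± 65.6 (adjusted p = 0.108). For the dendritic cell list camera gave adjusted p = 0.0029, and adjusted p = 0.258 with an estimated correlation. The 24 TNF and NF-kB response genes had a median of -0.54, with 0 lower over all genes and 3 adjusted over the list alone, led by TRAF1, CXCL8 and TNF. For the TNF and NF-kB list camera gave adjusted p = 0.000353, and adjusted p = 0.471 with an estimated correlation. T lymphocyte transcripts were higher in this class (median 0.58, 0 over all genes and 7 of 11 adjusted over the list alone, camera adjusted p = 8.91e-06, adjusted p = 0.311 with an estimated correlation). Fibroblast transcripts were lower (median -0.335, 0 past the threshold either way, camera adjusted p = 0.011, adjusted p = 0.437 with an estimated correlation), but 0.05 without healthy 1 (adjusted p = 0.756) and -1.332 without healthy 3. Genes of dissociation and immediate early stress were lower (median -0.279, 0 of 22 past the threshold either way, camera adjusted p = 0.00169, adjusted p = 0.398 with an estimated correlation), with -0.169 without healthy 1 (adjusted p = 0.105) and -0.545 without healthy 3. Without healthy 3 the medians of the metallothionein, IFN-gamma response, lipid-handling and T lymphocyte lists moved to 4.291, 1.842, 1.522 and 1.723. The pseudocount of that fit was smaller, so these medians are not on the scale of the full fit. Without granuloma annulare 2 those of the metallothionein and glycolysis lists moved to 1.296 and 0.515, and without granuloma annulare 1 that of the T lymphocyte list to 0.37. The median of the TNF and NF-kB list ran from -0.816 without granuloma annulare 3 to -0.209 without healthy 1. Granuloma annulare cells lay mostly in cluster 18, with 248, 89 and 64 cells, and healthy ones in clusters 17 and 23. Leading genes of cluster 18 included SPP1, FBP1, C1QA and MARCO. Those of cluster 17 included CCL22, CCL17, CLEC10A and CD1E, and those of cluster 23 C1QA, FOLR2 and CD163. The mix of clusters thus differed between the groups, and no change was tested within a cluster. Changes in this class therefore hold both that mix and any change within cells.

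**Figure D3:**
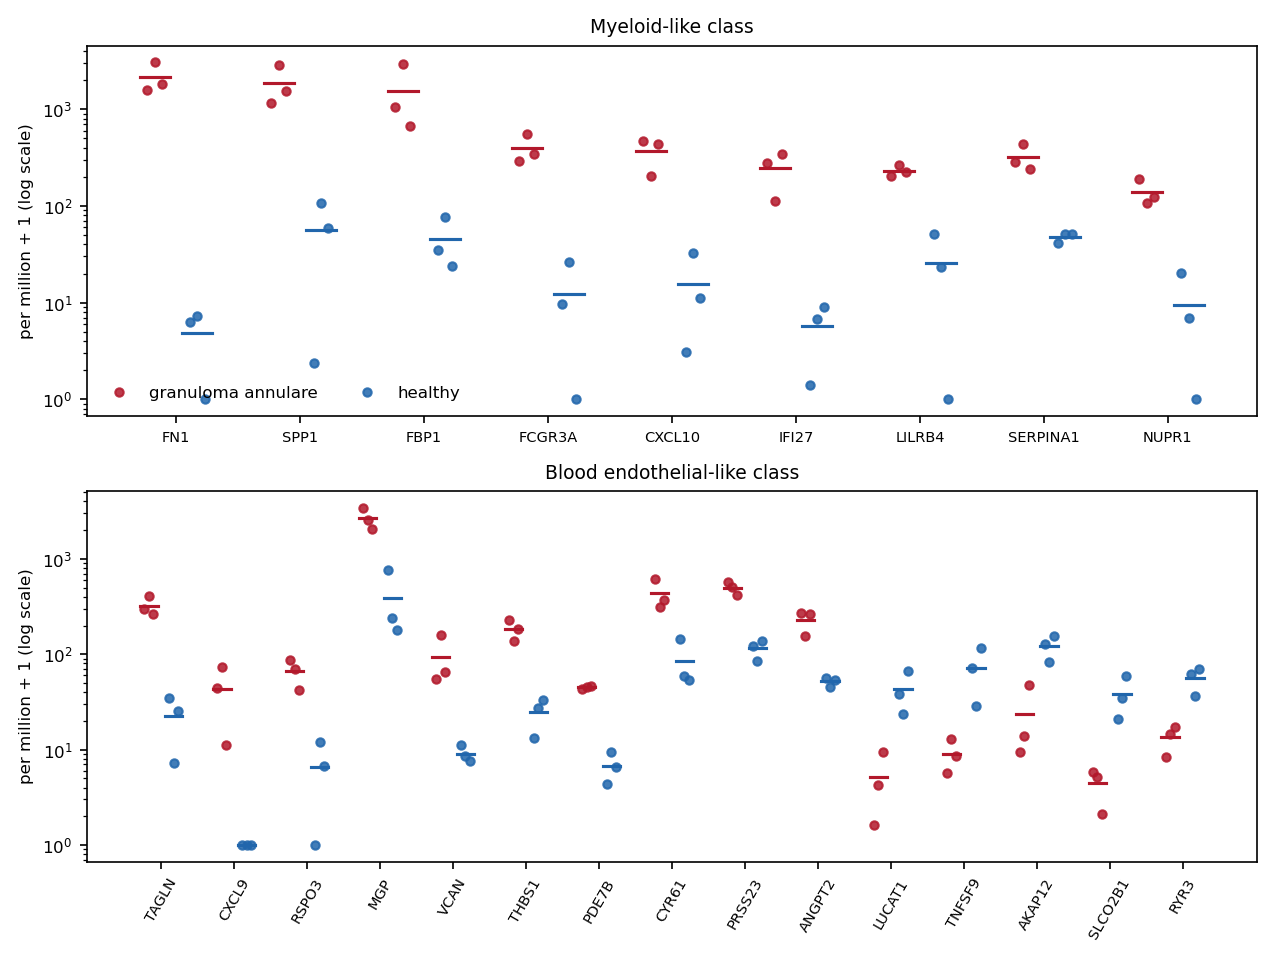
Levels (UMIs per 1000000 plus 1, log axis) of the genes named first in the myeloid-like class, above, and in the blood endothelial-like class, below, 1 point per biopsy of granuloma annulare or healthy skin. FN1 in the myeloid-like class averaged 2167 against 3.84, and TAGLN in the blood endothelial-like class 323 against 21.5.

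In the fibroblast-like class, 4 genes rose. MME, which encodes the cell surface peptidase CD10 (chromosome 3, 155024124 to 155183729), rose from 6.96 ± 7.51 to 135 ± 41.3 (log2 3.51 ± 0.40, adjusted p = 0.00643). SULF1, a sulfatase of heparan sulfate (chromosome 8, 69466624 to 69660915), rose from 8.27 ± 4.06 to 94.8 ± 7.66 (log2 2.84 ± 0.33, adjusted p = 0.00643). The metalloprotease genes ADAMDEC1 and ADAM12 rose from 9.20 ± 11.9 to 121 ± 16.7 (adjusted p = 0.0268) and from 2.53 ± 2.82 to 38.5 ± 11.5 (adjusted p = 0.0414). CXCL9, an interferon-induced chemokine that attracts T cells (chromosome 4, 76001275 to 76007488), averaged 629 ± 578 against 4.31 ± 6.20 without passing (log2 5.39 ± 0.83, adjusted p = 0.0986). COL1A1 and COL3A1, the main dermal collagens, had log2 differences of -0.11 and 0.47, and IL15 and IL6 of -0.04 and 0.42, none past the threshold.

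Of the 11040 genes tested in the fibroblast-like class, 4 rose and 0 fell (limma, 678 with an unadjusted p under 0.05, and 3 called by voom on sums of UMIs). Leaving out granuloma annulare 1, 2 and 3 gave 3, 9 and 6 genes. Leaving out healthy 1, 2 and 3 gave 86, 8 and 0 (limma, 510 with an unadjusted p under 0.05 in the fit that called 0), and without healthy 3 MME had an adjusted p of 0.0947, SULF1 of 0.05, ADAMDEC1 of 0.685 and ADAM12 of 0.379. ADAMDEC1 also lost the call without granuloma annulare 1 and 3 (0.109 and 0.0955), and ADAM12 without granuloma annulare 1, 2 and 3 (0.154, 0.0991 and 0.0712). Healthy 1 held 475 of the fibroblast-like cells, most of them in cluster 16, apart from cluster 9 that held most cells of the other samples.

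The 26 tested IFN-gamma response genes had in the fibroblast-like class a median log2 difference of 1.24, with 0 higher over all genes and 16 adjusted over the list alone. For the IFN-gamma response camera gave adjusted p = 9.55e-16, and adjusted p = 0.209 with an estimated correlation. GBP1 was 219 ± 119 against 38.7 ± 19.8 and GBP4 70.2 ± 28.9 against 16.8 ± 5.13, while IDO1, with no UMI in the healthy samples, was at least 3.16-fold higher against a floor of 3 UMIs in each healthy library. HLA class I presentation genes had a median of 0.74, with 0 over all genes and 4 of 17 adjusted over the list alone, HLA-B at 2564 ± 187 against 1118 ± 301. For the HLA class I list camera gave adjusted p = 5.75e-09, and adjusted p = 0.202 with an estimated correlation. Type I interferon response genes had a median of 0.63, with 0 over all genes and 7 of 25 adjusted over the list alone, led by IFI44L, EPSTI1, IFIT3 and IFI6. For the type I interferon list camera gave adjusted p = 1.52e-08, and adjusted p = 0.202 with an estimated correlation. The 16 myofibroblast genes had a median of 1.10, with 1 higher over all genes, ADAM12, and 5 adjusted over the list alone, SFRP4, CDH11 and CTHRC1 following with log2 differences of 2.09, 1.57 and 2.17. For the myofibroblast list camera gave adjusted p = 4.59e-08, and adjusted p = 0.231 with an estimated correlation. The 17 matrix proteases and inhibitors had a median of 0.48, with 0 higher over all genes and 5 adjusted over the list alone. For the matrix protease list camera gave adjusted p = 0.000365, and adjusted p = 0.226 with an estimated correlation. MMP9, a gelatinase, averaged 35.9 ± 15.3 against 2.10 ± 1.82 (adjusted p = 0.0598) and TIMP1, a protease inhibitor, 4940 ± 3113 against 710 ± 255 (adjusted p = 0.208). T lymphocyte transcripts were also higher in this class (median 1.00, 0 over all genes and 2 of 9 adjusted over the list alone, camera adjusted p = 2.02e-06, adjusted p = 0.301 with an estimated correlation), CCL5 at 118 ± 85.0 against 8.86 ± 10.3. The 3 tested macrophage and dendritic transcripts had a median of 1.368, with 0 over all genes and 2 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.106, adjusted p = 0.409 with an estimated correlation). The 3 erythroid transcripts were lower (median -1.97, 0 over all genes and 3 adjusted over the list alone, camera adjusted p = 3.4e-06, adjusted p = 0.202 with an estimated correlation). Genes of dissociation and immediate early stress were lower too (median -0.52, 0 of 22 past the threshold either way, camera adjusted p = 1.56e-05, adjusted p = 0.202 with an estimated correlation), NR4A1 at 337 ± 119 against 1004 ± 493. Without 1 sample the median of the myofibroblast list moved to 0.705 (granuloma annulare 2) or 0.534 (healthy 1). The median of the matrix protease list moved to 0.284 (granuloma annulare 2) and that of the T lymphocyte transcripts to 1.525, 1.519 or 1.564 (granuloma annulare 2, healthy 2 or healthy 3).

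In the blood endothelial-like class, TAGLN, an actin-binding gene of contractile cells (chromosome 11, 117199321 to 117204782), rose from 21.5 ± 14.02 to 323 ± 76.4 (log2 3.87 ± 0.43, adjusted p = 0.00424). THBS1, which encodes the matrix protein thrombospondin 1 (chromosome 15, 39581079 to 39599466), rose from 23.8 ± 10.3 to 183 ± 43.9 (log2 2.81, adjusted p = 0.00424). ANGPT2, a regulator of vessel remodelling, rose from 50.9 ± 5.63 to 229 ± 66.0 (adjusted p = 0.0103), and the basement membrane genes COL4A1, COL4A2 and LAMA4 rose by log2 differences of 1.99, 1.66 and 1.84 (adjusted p = 0.0279, 0.0368 and 0.0425). The proteoglycan gene VCAN rose from 8.09 ± 1.85 to 92.9 ± 58.0 (adjusted p = 0.00668), MGP, an inhibitor of calcification, from 391 ± 317 to 2670 ± 686 (adjusted p = 0.0213) and RSPO3, an activator of Wnt signalling, from 5.55 ± 5.48 to 65.6 ± 22.9 (adjusted p = 0.0102). CXCL9 rose from no UMI to 42.0 ± 31.3, at least 15-fold higher against a floor of 3 UMIs in each healthy library (adjusted p = 0.0102), and CXCL11, another interferon-induced chemokine, rose by 2.56 (adjusted p = 0.0102). PDE7B, CYR61 and PRSS23 also rose, by log2 differences of 2.38, 2.37 and 2.08. LUCAT1, TNFSF9, AKAP12, SLCO2B1 and RYR3 fell, by log2 differences of -2.62, -2.57, -2.53, -2.51 and -1.90, TNFSF9 being a ligand that costimulates T cells. ICAM1, an adhesion molecule for leukocytes, averaged 339 ± 245 against 1198 ± 748 (log2 -1.85, adjusted p = 0.238), and VCAM1, SELE and IL15 had log2 differences of 1.44, -1.22 and 0.85, none past the threshold.

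Of the 10906 genes tested in the blood endothelial-like class, 20 rose and 5 fell, and 899 had an unadjusted p under 0.05. With voom on sums of UMIs 34 were higher and 31 lower, and without healthy 1 these were 33 and 21. TAGLN and THBS1 passed in all 6 fits that left out 1 sample, and all other genes named here as changed lost the call without healthy 3. The number changed was 15, 24 and 37 without granuloma annulare 1, 2 and 3 and 54, 5 and 2 without healthy 1, 2 and 3, and CXCL9 had an adjusted p of 0.0704 without healthy 2 and 0.0706 without healthy 3. Cells of granuloma annulare 1 and 2 lay mostly in cluster 10 (530 and 123 cells), while granuloma annulare 3 had 39 cells there and 137 in cluster 5, which held most healthy cells, with 784 from healthy 3.

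The 14 angiogenesis and tip cell genes had in the blood endothelial-like class a median log2 difference of 0.87, with 4 higher over all genes and, adjusted over the list alone, 6 higher and 1 lower. For the angiogenesis list camera gave adjusted p = 4.63e-05, and adjusted p = 0.226 with an estimated correlation. The 27 IFN-gamma response genes had a median of 0.33, with 2 higher over all genes, CXCL9 and CXCL11, and, adjusted over the list alone, 8 higher and 1 lower. For the IFN-gamma response camera gave adjusted p = 0.007, and adjusted p = 0.226 with an estimated correlation. The 18 TNF and NF-kB response genes had a median of -0.82, with 0 lower over all genes and 2 adjusted over the list alone, IL6 at 220 ± 120 against 876 ± 606, ICAM1 and TNFAIP3 being among its leading members. For the TNF and NF-kB list camera gave adjusted p = 5.54e-06, and adjusted p = 0.398 with an estimated correlation. The 4 tested cytokines that signal through JAK and STAT proteins had a median of -1.31, with 0 past the threshold over all genes and, adjusted over the list alone, 1 higher, IL15, and 2 lower, IL6 and CSF3. For the cytokine list camera gave adjusted p = 0.00967, or 0.0519 without healthy 1, and adjusted p = 0.228 with an estimated correlation, and with no filter on low values its median was 0.041 (adjusted p = 0.426). Genes of dissociation and immediate early stress were lower here as well (median -0.55, 0 of 22 past the threshold either way, camera adjusted p = 1.94e-06, adjusted p = 0.275 with an estimated correlation). Fibroblast transcripts were lower (median -1.107, camera adjusted p = 0.00896, adjusted p = 0.456 with an estimated correlation), as were erythroid ones (median -0.696, camera adjusted p = 0.027, adjusted p = 0.399 with an estimated correlation), both with 0 past the threshold either way. The fibroblast call was lost without healthy 1 and 3 (medians -0.41 and -0.685, adjusted p = 0.589 and 0.0878) and had a median of -1.815 without healthy 2. The erythroid call was lost without granuloma annulare 3 and healthy 2 (adjusted p = 0.0952 and 0.469) and had a median of -1.5 without healthy 1. The TNF and NF-kB median moved to -0.371 and -1.272 without granuloma annulare 2 and 3, and the stress median to -0.283 without healthy 1.

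In the mural-like class, the pericytes and smooth muscle of vessels by their markers, CCL21, a chemokine that attracts CCR7-bearing cells (chromosome 9, 34709005 to 34710124), rose from 54.3 ± 58.0 to 1046 ± 582 (log2 4.05 ± 0.57, adjusted p = 0.0117). CCL21 is also among the lymphatic endothelial markers used here, and a leading gene of the lymphatic endothelial-like cluster. RNA or cells of lymphatic endothelium were not tested as its source. CXCL9 rose from 0.378 ± 0.655 to 189 ± 116 (log2 3.72 ± 0.49, adjusted p = 0.0111), RARRES3 from 5.29 ± 8.18 to 85.1 ± 27.2 (adjusted p = 0.0471) and GBP4 from 10.3 ± 6.30 to 104 ± 30.1 (adjusted p = 0.0471). CCL2, a chemokine that attracts monocytes (chromosome 17, 34255218 to 34257203), fell from 4775 ± 1133 to 1057 ± 392 (log2 -2.34 ± 0.36, adjusted p = 0.0194), and DDIT4, a stress-induced inhibitor of mTOR, from 458 ± 255 to 61.5 ± 31.7 (adjusted p = 0.0234). Of 6088 genes tested, 5 rose and 2 fell, and 484 had an unadjusted p under 0.05. The balance turned with voom on sums of UMIs, 6 higher and 15 lower, and without healthy 1, 24 higher and 58 lower. The number changed was 2, 2 and 1 without granuloma annulare 1, 2 and 3 and 82, 7 and 4 without healthy 1, 2 and 3. No gene passed in all 6 of these fits. CXCL9 lost the call without granuloma annulare 1 and 3 (adjusted p = 0.106 and 0.0592), and CCL21 without granuloma annulare 2 and 3 and healthy 2 (0.0764, 0.0508 and 0.0636). CCL2 lost it without each granuloma annulare sample and healthy 2 (highest 0.105) and RARRES3 without each granuloma annulare sample and healthy 3 (highest 0.617). GBP4 and DDIT4 lost it in all these fits but the one without healthy 1 (highest 0.428 and 0.101). With the per-cell scaling alone, the median log2 difference over all genes was 0.131 rather than 0.014, and 9 genes were higher and 2 lower.

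The 15 TNF and NF-kB response genes had in the mural-like class a median log2 difference of -1.42, with 1 lower over all genes, CCL2, and 7 adjusted over the list alone, CXCL2, NFKBIA and NFKBIZ following with -2.32, -1.86 and -1.55. For the TNF and NF-kB list camera gave adjusted p = 4.03e-11, and adjusted p = 0.226 with an estimated correlation. The 20 IFN-gamma response genes had a median of 0.93, with 2 higher over all genes, CXCL9 and GBP4, and, adjusted over the list alone, 8 higher and 1 lower, IRF1 being 404 ± 113 against 1499 ± 515 (camera adjusted p = 4.4e-08, adjusted p = 0.226 with an estimated correlation). The 5 tested complement genes had a median of 1.99, with 0 higher over all genes and 4 adjusted over the list alone, C1S at 884 ± 462 against 112 ± 27.1. C1S is also among the fibroblast markers used here, and RNA of fibroblasts was not tested as its source. For the complement list camera gave adjusted p = 3.83e-07, and adjusted p = 0.226 with an estimated correlation. HLA class I presentation genes had a median of 0.88, with 0 over all genes and 5 of 15 adjusted over the list alone. For the HLA class I list camera gave adjusted p = 2.7e-07, and adjusted p = 0.271 with an estimated correlation. Fibroblast transcripts were higher (median 0.64, 0 over all genes and 1 of 10 adjusted over the list alone, camera adjusted p = 0.00099, adjusted p = 0.273 with an estimated correlation), and stress genes were lower (median -0.74, 0 over all genes and 1 of 22 adjusted over the list alone, camera adjusted p = 2.05e-06, adjusted p = 0.258 with an estimated correlation). Without healthy 3 the TNF and NF-kB median moved to -0.878.

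The keratinocyte-like class could be tested in 2 biopsies per group, granuloma annulare 1 and 3 and healthy 2 and 3, and its cells were few. IFI27 rose from 40.3 ± 12.4 to 1467 ± 143 (SD, n = 2, log2 5.08 ± 0.64, adjusted p = 0.000119), and IFI6, also interferon-stimulated, rose by 3.57 (adjusted p = 0.0132, but 0.402, 0.0707 and 0.146 without granuloma annulare 3, healthy 2 and healthy 3). Genes of sweat glands were higher in the biopsies tested as well, MUCL1 from no UMI to 5151 ± 2734, at least 1100-fold against a floor of 3 UMIs in each of healthy 2 and 3 (adjusted p = 3.73e-08) and KRT19 from no UMI to 794 ± 271, at least 170-fold (adjusted p = 7.6e-06). Of the 10 tested sweat gland genes 8 were higher over all genes and 10 adjusted over the list alone (median 5.87, or 7.29 with the genes at 0 set to their lower bounds, camera adjusted p = 1.91e-49, adjusted p = 0.202 with an estimated correlation). Cells with at least 3 of 11 sweat gland genes numbered 6, 2 and 5 of the 27, 8 and 15 keratinocyte-like cells of granuloma annulare 1, 2 and 3, and 6, 0 and 0 of the 7, 58 and 124 of healthy 1, 2 and 3. Healthy 1, left out of the test for its few cells, thus had the highest share of such cells and goes against a difference between the groups. The 7 tested type I interferon response genes had a median of 1.05, with 2 higher over all genes and 3 adjusted over the list alone. For the type I interferon list camera gave adjusted p = 5.22e-07, and adjusted p = 0.226 with an estimated correlation, with a median of 1.93 without granuloma annulare 1. T lymphocyte transcripts were higher as well (median 1.288, 0 over all genes and 2 of 4 adjusted over the list alone, camera adjusted p = 0.00909, adjusted p = 0.399 with an estimated correlation, and a median of 2.189 without granuloma annulare 3). Fibroblast transcripts were lower (median -1.58, 0 over all genes and 2 of 5 adjusted over the list alone, camera adjusted p = 5.49e-06, adjusted p = 0.226 with an estimated correlation). KRT6A and KRT16, keratins of wounded and psoriatic epidermis, had log2 differences of 3.06 and 2.19, neither past the threshold. In all, 24 of 5824 genes rose and 1 fell (381 with an unadjusted p under 0.05), which became 259, 46, 20 and 19 without granuloma annulare 1, granuloma annulare 3, healthy 2 and healthy 3 in turn, and 2 without the cells with sweat gland genes.

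Across the classes, camera at the preset correlation called the IFN-gamma response list higher in all 6, and 0 of these calls held with an estimated correlation. Outside the keratinocyte-like class the call at the preset correlation held in each fit that left out 1 sample. In the keratinocyte-like class its 15 tested genes had a median log2 difference of 1.49, with 0 past the threshold either way (camera adjusted p = 0.000113, adjusted p = 0.228 with an estimated correlation). CXCL9 passed in the blood endothelial-like and mural-like classes, GBP4 in the T/NK-like and mural-like classes, and IFI27 in the myeloid-like and keratinocyte-like classes. Of all 138 pairs of list and class, camera called 46 higher and 26 lower, but 0 with an estimated correlation (lowest adjusted p 0.202, 29 pairs with an unadjusted p under 0.05) and 1 by fry, HLA class I presentation in the myeloid-like class (adjusted p = 0.0383). By the test of the difference between classes, the IFN-gamma response rose less in the blood endothelial-like than in the fibroblast-like class (median difference 0.93, camera adjusted p = 4.39e-09, adjusted p = 0.444 with an estimated correlation), and HLA class I presentation differed between the blood endothelial-like and myeloid-like classes (median difference 1.14, camera adjusted p = 4.92e-15, adjusted p = 0.444 with an estimated correlation). The latter list was not called in the blood endothelial-like class (median -0.012, camera adjusted p = 0.817, adjusted p = 0.943 with an estimated correlation).

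**Figure D4:**
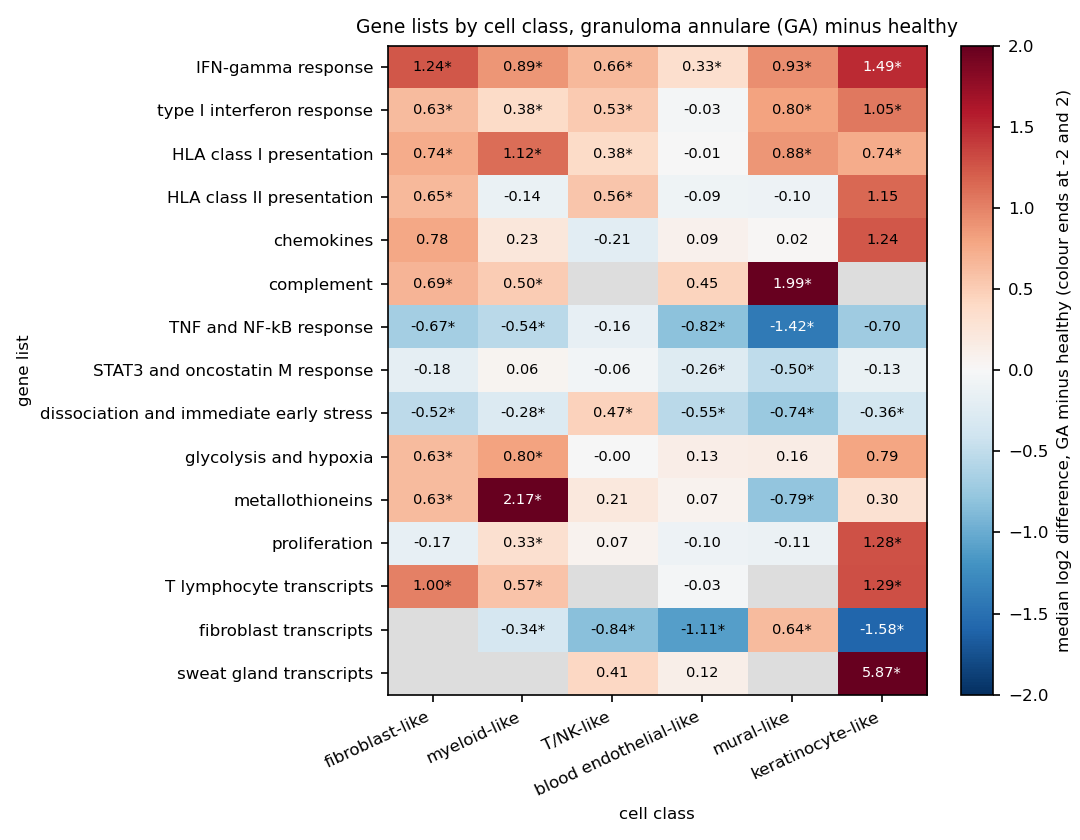
Median log2 difference of each gene list, granuloma annulare minus healthy, by cell class, with a star where the camera adjusted p was under 0.05 and grey where the list was not tested. The IFN-gamma response list was above 0 in all 6 classes, from 0.33 in the blood endothelial-like to 1.49 in the keratinocyte-like class, and no star remained with an estimated correlation.

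The classes that held the UMIs of cytokine genes were compared within the granuloma annulare samples. T/NK-like cells held 96.0% ± 3.13 (SD, n = 3) of the IFNG UMIs of a sample, and in healthy skin 96.3% ± 2.63. They held all 336 UMIs of IL21, a cytokine of helper T cells, and 66.7% ± 11.9 of those of TNF. Myeloid-like cells held 76.2% ± 20.2 of the CXCL10 UMIs and 37.2% ± 15.2 of the CXCL9 UMIs, and fibroblast-like cells 47.4% ± 25.2 of the latter. OSM, which encodes oncostatin M, came from T/NK-like cells for 50.3% ± 11.8 and from myeloid-like cells for 42.7% ± 12.7 of its UMIs. Blood endothelial-like cells held 47.0% ± 14.3 of the UMIs of IL15 and 63.8% ± 4.91 of those of IL6. These shares depend on how many cells of each class a biopsy yielded.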

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

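The tests of FN1 without healthy 3 and all tests of CXCL9 in this part were chosen after the result was seen, whereas the predictions for RNA of other cell classes behind FN1, TAGLN and VCAN were written before. Each gene below except CXCL9 was singled out because its change in granuloma annulare differed between cell classes in the limma test of that difference itself, with n = 3 biopsies per group and adjustment over the genes of each pair of classes.

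FN1, the fibronectin gene, rose more in the myeloid-like class than in the fibroblast-like class (fibroblast-like minus myeloid-like -4.62, adjusted p = 0.00336), the T/NK-like class (myeloid-like minus T/NK-like 4.997, adjusted p = 0.0241) and the mural-like class (myeloid-like minus mural-like 4.09, adjusted p = 0.0153). RNA or cells of fibroblasts in the myeloid-like class would need a share of 0.941 to 1.54 of its RNA to give the FN1 level seen, yet the median of COL1A1, COL1A2, COL3A1, DCN and LUM reached at most 0.00125 of the level such a share brings, which argues against that source. Shallow sequencing of healthy 3 is argued against as the whole cause, since FN1 stayed past the threshold without that sample. Its log2 difference was 8.26 in that fit. The larger size says nothing on the cause, as the pseudocount shrank to 2 UMIs of the shallowest library left. The class held a different mix of clusters in granuloma annulare and healthy skin. Cluster 18, led by genes such as SPP1, C1QA and MARCO, held 248, 89 and 64 cells of granuloma annulare 1, 2 and 3. It held 3, 10 and 0 cells of healthy 1, 2 and 3. Healthy cells lay mostly in cluster 17, with CCL22 and CD1E among its leading genes, and in cluster 23, with C1QA and CD163. What stays open is whether FN1 also changed within a kind of cell, which was not tested. Macrophages that make fibronectin in the disease may be behind the change, a hypothesis that the group design cannot part from person or day of biopsy.

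TAGLN had a myeloid-like minus blood endothelial-like difference of -3.99 (adjusted p = 0.00914) and a T/NK-like minus blood endothelial-like one of -3.99 (adjusted p = 0.0161). VCAN had a T/NK-like minus blood endothelial-like difference of -3.15 (adjusted p = 0.0324). THBS1 had a fibroblast-like minus blood endothelial-like difference of -3.89 (adjusted p = 0.0388). These exceed in size the rises of TAGLN, VCAN and THBS1 in the blood endothelial-like class (3.87, 2.89 and 2.81). By the point estimates the genes therefore did not rise in the classes compared with it. For TAGLN and VCAN the excess was smaller than the SE of the differences (0.418 and 0.503 for TAGLN, 0.449 for VCAN). The pseudocount was 3.46 in the blood endothelial-like class and larger in the classes compared (6.65 to 32.7). Rises of low-level genes were thus understated more in those classes, and a small rise there is not excluded. RNA of mural cells is argued against as the whole source of TAGLN, as the median of RGS5, ACTA2, MYH11, MYL9 and NDUFA4L2 reached at most 0.0865 of the level that the needed share would bring. Of these 5, MYL9 did reach that level, at 1.78, 1.22 and 1.62 times it in granuloma annulare 1, 2 and 3, while the other 4 reached at most 0.371 of it, and ACTA2, the most abundant of them in the mural-like class, at most 0.0575. RNA of fibroblasts is argued against for VCAN, as the median of 5 fibroblast genes reached at most 0.00956 of that level. Neither test covers THBS1. Remodelling of vessels in the disease may be behind the rise, as a hypothesis, and a different mix of vessel cells remains open, since cells of granuloma annulare 1 and 2 lay mostly in another cluster than healthy ones, though most cells of granuloma annulare 3 shared the cluster of the healthy ones.

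The test between classes did not call CXCL9 for any pair. It was higher in granuloma annulare in the fibroblast-like class, without passing the test, and rose in the mural-like and blood endothelial-like classes. Free RNA that reaches all droplets alike is argued against in the fibroblast-like and mural-like classes, where the CXCL9 level was at least 85 times that of the T/NK-like class of the same sample in all 3 samples (lowest counting bound 55.6). In the blood endothelial-like class that ratio was 22.7, 187 and 3.68 in granuloma annulare 1, 2 and 3, with a counting bound of 2.31 for the last, so free RNA stays open there. RNA of fibroblasts stays open in the mural-like class, where the median of 5 fibroblast genes reached up to 0.487 of the level it would bring, and is argued against in the blood endothelial-like class, where it reached at most 0.0565. A response of fibroblasts to the IFNG made by T/NK-like cells may be behind the higher CXCL9 level, which these biopsies cannot test.

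ADAM12, a metalloprotease gene, had a fibroblast-like minus myeloid-like difference of 2.69 (adjusted p = 0.0162). Its fibroblast-like minus T/NK-like difference was 3.38 (adjusted p = 0.0208). Both exceed its log2 difference of 2.35 in the fibroblast-like class, so by the point estimates it did not rise in the other 2 classes. The pseudocount was larger in those 2 classes, so a small rise there is not excluded. MMP9, a gelatinase gene, had a fibroblast-like minus T/NK-like difference of 3.76 (adjusted p = 0.0208). DDIT4, a stress-induced gene, had a myeloid-like minus mural-like difference of 3.88 (adjusted p = 0.0153). GIMAP7, GIMAP4 and KLF2, genes of resting lymphocytes that KLF2 helps to keep in circulation, had T/NK-like minus blood endothelial-like differences of 1.957, 2.31 and 2.43 (adjusted p = 0.043, 0.0161 and 0.0161).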

How the results depend on the processing

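Chosen after the results were seen were the tests with the per-cell scaling alone, with other pseudocounts, on sums of UMIs with and without voom weights, without shallow clusters and without cells with sweat gland transcripts, while the other alternatives were planned. Counts of changed genes are given in the order fibroblast-like, myeloid-like, T/NK-like, blood endothelial-like, mural-like and keratinocyte-like, and stood at 4, 9, 9, 25, 7 and 25. The cause was not tested unless stated. With no filter on low values, which adds genes near 0, they were 0, 1, 0, 0, 3 and 39 (limma, with 918, 1361, 1373, 1281 and 926 genes at an unadjusted p under 0.05 in the first 5). A pseudocount of 2 UMIs of the mean library gave 0, 0 and 0 in the first 3 classes (limma, 643, 703 and 809 at an unadjusted p under 0.05) and 4 in the mural-like class. The per-cell scaling alone gave 2 in the fibroblast-like, 4 in the T/NK-like, 11 in the mural-like and 44 in the keratinocyte-like class, where the median over all genes moved from 0.04 to -0.075. A pseudocount of 0.5 UMIs gave 2 in the fibroblast-like and 4 in the mural-like class, and one of 8 UMIs gave 14 in the T/NK-like, 13 in the mural-like and 16 in the keratinocyte-like class. Sums of UMIs gave 22 in the myeloid-like, 38 in the blood endothelial-like, 15 in the mural-like and 4 in the keratinocyte-like class, and voom weights on them gave 47, 41, 65, 21 and 2 in the myeloid-like, T/NK-like, blood endothelial-like, mural-like and keratinocyte-like classes (37, 19, 34, 6 and 2 higher). The stricter cell filter gave 4 in the mural-like class, leaving out shallow clusters 3 in the T/NK-like class, Leiden resolution 0.5 gave 2 in the keratinocyte-like class, and leaving out cells with sweat gland transcripts also gave 2 there.

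Leaving out 1 sample at a time gave 0 to 86 genes in the fibroblast-like, 6 to 51 in the myeloid-like, 0 to 52 in the T/NK-like, 2 to 54 in the blood endothelial-like, 1 to 82 in the mural-like and 19 to 259 in the keratinocyte-like class. The highest counts came without healthy 1 in the first 5 classes, with 43, 30, 29, 33 and 24 genes higher and 43, 21, 23, 21 and 58 lower. In the keratinocyte-like class each such fit leaves a single sample in one group, which is assumed to vary like the other group. The number of class shares without overlap was 2, with 2 to 5 when 1 sample was left out, 1 among immune cells alone and 1 at Leiden resolution 0.5.

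With the label's number as a replicate block, which pairs nobody, 35, 23, 74, 154 and 32 genes changed in the first 5 classes. No paired analysis was possible because the numbers count people within a group, and in the keratinocyte-like class the groups tested share 1 number, so no block was fitted there.

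Of the 72 list calls, 0 were kept by camera with an estimated correlation (29 pairs at an unadjusted p under 0.05, 1 by fry). Over all alternatives, list calls kept their direction and their side of the threshold 1306 times, lost the call 124 times including those with an estimated correlation, and turned in direction against the other genes of the class 4 times. In these counts the replicate block and the fits without granuloma annulare 2 or healthy 1 leave the keratinocyte-like class as it was. The fit without cells with sweat gland transcripts leaves all other classes as they were. List calls carried over in this way count as kept, so that count overstates how often calls were retested. The 4 turns were the endothelial transcripts in the T/NK-like class (median -0.449, and -0.88 to 0.68 without 1 sample, the highest without healthy 3), the cytokines that signal through JAK and STAT proteins in the blood endothelial-like class with no filter (from -1.31 to 0.041), the fibroblast transcripts in the keratinocyte-like class at Leiden resolution 0.5 (from -1.58 to -0.17, still below 0, with a median of 0.189 over all genes and a camera adjusted p of 0.987) and the keratinocyte injury genes (1.81, and -1.60 to 3.27 without 1 sample, the lowest without granuloma annulare 1). The uncalled gene S100A8 in the keratinocyte-like class ran from -3.62 without granuloma annulare 1 to 5.39 without granuloma annulare 3. Called genes kept their call 779 times and lost it 305 times, always in the same direction. The second count test planned for the comparison was not run on the worked-back UMIs, for which voom was used. With the depth and the number of samples at hand, whose parts were not told apart, the self-test recovered 18.5%, 4.7%, 10.8%, 13.6%, 17.2% and 0% of 2-fold changes in the 6 classes, so smaller changes were mostly not detectable.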

Other observations

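The tests over other splits of the samples were chosen after the result was seen, while the gene lists below were fixed beforehand. In the fibroblast-like class, glycolysis and hypoxia genes had a median log2 difference of 0.63, with 0 of 18 past the threshold either way, the lipid droplet gene HILPDA at 70.7 ± 37.6 against 23.5 ± 1.85 (SD, n = 3). For the glycolysis and hypoxia list, with a median of 0.384 without granuloma annulare 2, camera gave adjusted p = 0.000193, and adjusted p = 0.398 with an estimated correlation. TNF and NF-kB response genes had a median of -0.67, with 0 of 20 past the threshold either way, CCL2 at 241 ± 83.5 against 703 ± 214, and camera called them no longer without granuloma annulare 2 (median -0.219, adjusted p = 0.117). That median was -1.103 without granuloma annulare 3 and -0.303 without healthy 3. For the TNF and NF-kB list camera gave adjusted p = 5.72e-05, and adjusted p = 0.471 with an estimated correlation. WIF1, a Wnt inhibitor of the papillary dermis, averaged 1.63 ± 2.04 against 77.3 ± 60.7 without passing (adjusted p = 0.0899).

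In the myeloid-like class, proliferation genes had a median of 0.33, with 0 over all genes and 1 of 16 adjusted over the list alone, led by BIRC5 and CCNB1. For the proliferation list, with a median of 0.829 without healthy 3, camera gave adjusted p = 0.00099, and adjusted p = 0.399 with an estimated correlation. Complement genes had a median of 0.50, with 0 over all genes and 4 of 12 adjusted over the list alone, C1QB at 1077 ± 144 against 297 ± 309. For the complement list, with medians of 0.841 and 1.032 without healthy 1 and 3, camera gave adjusted p = 0.00073, and adjusted p = 0.409 with an estimated correlation. In the T/NK-like class, genes of dissociation and immediate early stress were higher, where the list was called lower in the other 5 classes (median 0.47, 0 over all genes and 2 of 22 adjusted over the list alone, camera adjusted p = 0.00149, adjusted p = 0.371 with an estimated correlation, 0.0831 by camera without healthy 1, and a median of 0.303 without healthy 3), JUN at 1307 ± 262 against 408 ± 168. Of the lower ones, the keratinocyte-like list had a median of -0.365, with 0 of 22 past the threshold either way (camera adjusted p = 0.00734, adjusted p = 0.276 with an estimated correlation). That call was lost without granuloma annulare 1 and 3 (adjusted p = 0.0627 and 0.153), and its median was -0.236 without healthy 2. The test of the difference itself called the stress list between the fibroblast-like and T/NK-like classes (median difference -1.08, camera adjusted p = 8.31e-12, adjusted p = 0.444 with an estimated correlation). In the mural-like class, genes of the STAT3 and oncostatin M response had a median of -0.50, with 1 lower over all genes, CCL2, and 2 of 17 adjusted over the list alone. For the STAT3 list camera gave adjusted p = 0.00124, and adjusted p = 0.226 with an estimated correlation.

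A cluster whose leading genes were those of plasmacytoid dendritic cells, among them LILRA4 and GZMB, was left without a class name. It held 40, 9 and 23 cells of granuloma annulare 1, 2 and 3 and 2 cells of healthy 2. It held 0 of the 790 cells of healthy 1 and 0 of the 2406 of healthy 3, which allows shares of up to 0.38% and 0.125%.

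In the other splits of the 6 samples into 3 and 3, of which there are 10 with the real one, 1 split, the real one, gave as many genes as the real comparison in each of 5 classes. The real split changed 4 genes in the fibroblast-like class and the highest other 1. In the myeloid-like and T/NK-like classes the real split changed 9 and 9 genes and the highest other 0 and 0. In the blood endothelial-like and mural-like classes the real split changed 25 and 7 and the highest other 0 and 0. The 10 splits are too few for a share under 0.05.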
